A study of Homo sapiens with 12 samples.

How the data were processed

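Total RNA was measured by RNA sequencing in MDA-MB-231 cells, an established human triple-negative breast cancer line with a mesenchymal character. The design holds 4 groups of 3 libraries, 12 in all: cells given a sham short hairpin RNA (control), cells given an shRNA against SIRT1 (SIRT1 KD), cells given an shRNA against IGF2BP2 (IGF2BP2 KD), and cells given both (double KD). Per the labels' protocols, the hairpins were delivered by lentivirus made in HEK-293T cells, a human embryonic kidney line used to package virus, with Polybrene at 8 µg/mL. Cells were grown in RPMI-1640 with 10% serum and kept under puromycin at 2.0 µg/mL. RNA was taken with Trizol from flash-frozen cells, and 1 µg went into libraries made with a New England Biolabs Ultra II kit. The series' design text says that each condition was analysed in 3 independent runs; whether a run is a separate infection is not given in the sources used here, so p-values measure the spread between these runs. The hairpin sequences are also not given in the sources used here.

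The submitters' processing notes name CASAVA, STAR, DESeq2 and the build GRCh38.p13, without versions, and the gene annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap an antisense partner therefore cannot be told apart from it, and members of near-identical families, such as the replication-dependent histones and ribosomal proteins with their pseudogenes, may share reads. The main table holds a signal that the authors made from gene counts and deposited under named columns: counts divided by a size factor per library, for 60649 versioned Ensembl gene IDs, of which 60507 were matched by ID to a symbol in a gene name table and 58381 to GENCODE 29. In all 12 columns 100% of values were whole multiples of a single step, within 0.001 reads, so whole reads could be recovered. Another deposited table holds log2 ratios, which the authors computed for each library against control for 15209 protein-coding genes. A table of raw counts carries no column names, and its 12 columns were not used in any step.

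Column names of the main table are short codes. Codes for control, IGF2BP2 KD and double KD were read from the letters, and the remaining code was taken as SIRT1 KD by elimination. The table of log2 ratios names its columns in full. Over 8739 genes each of its columns matched the main-table column read as the same library with a standard deviation (SD) of the log2 difference of at most 1.01e-09, and every other column with at least 0.0795. This match had been seen before the codes were written down, so it was not a blind check.

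The test planned before the data were examined was edgeR's quasi-likelihood test on raw counts. Because the columns with names hold size-factor-normalised counts, the main test was limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with a mean for each of the 4 groups, all 12 libraries in the fit, and moderated variances with a trend and robust settings. Genes were kept with edgeR's filterByExpr (minimum count 10) on the recovered reads, which left 17576. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 in a comparison, and adjusted p-values in the text are from this limma fit unless another tool is named. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. There were 6 comparisons: each knockdown against control, the double KD against each single knockdown, and the interaction, which is the double KD minus SIRT1 KD difference less the IGF2BP2 KD minus control difference. A positive interaction means that the double KD lies above the sum of the single knockdown changes. Confidence intervals are 95% from the same fit.

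Named genes follow a rule fixed before the data were examined. For each comparison with control they are the 10 largest rises and 10 largest falls among protein-coding genes with adjusted p under 0.05, at least 5 CPM (counts scaled to a fixed library total) on average, and no overlap between the libraries of the groups; for the other comparisons 5 and 5. SIRT1, IGF2BP2 and ATP6V1A are named throughout, with up to 4 members of each gene list by adjusted p. The 27 gene lists were also fixed beforehand: sirtuins, the IGF2BP family with m6A machinery, IGF2BP-bound transcripts, v-ATPase subunits, lysosomal hydrolases, lysosomal membrane proteins, autophagy and MiT/TFE regulators, ESCRT and exosome genes, p53 targets, FOXO targets, NF-kB targets with the inflammatory secretome, interferon-stimulated genes, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, cell cycle, replication-dependent histones, cytosolic ribosomal proteins, the unfolded protein and integrated stress response, immediate-early and heat-shock genes, mesenchymal and matrix genes, secreted proteases, and markers of epithelial, fibroblast, immune and packaging cells. Lists were tested against all other genes with camera (preset correlation 0.01, two-sided, adjusted over the 27 lists of a comparison). With a correlation estimated from the libraries, none of the camera calls in any comparison held, and that adjusted p is given beside each call.

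Sequence matches were searched in the longest annotated 3′ UTR of each tested protein-coding gene in GENCODE 29 on GRCh38 (13131 genes). For each of 16247 7-mers found in at least 50 UTRs, the mean log2 fold change of genes with it was compared with that of genes without it, after a regression on UTR length, GC content and expression, as a z value. Genes are not independent replicates, so z ranks the 7-mers; a two-sided Bonferroni-adjusted p of 0.05 would need a z of -4.67. Coordinates are 1-based, from GENCODE 29 on GRCh38.

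Depth, as reads assigned to genes, ran from 15243152 in double KD replicate 2 to 22509142 in IGF2BP2 KD replicate 1. No pair of libraries of a group agreed within sampling noise: the lowest chi-square per gene within a group was 2.34, between SIRT1 KD replicates 2 and 3. On data simulated from the real means and library sizes, the limma step recovered 82.9% of genes changed 1.5-fold and 98.3% of those changed 2-fold for SIRT1 KD against control, and 56.3% and 88.2% for the interaction; 6.03% and 4.65% of the calls were unchanged genes. In a simulated set of lists, camera called the list that had been moved and 1 of the 26 others. In these simulations each gene had the same dispersion in all groups, and genes varied independently. In the real data the median SD within a group was 0.2 in double KD and 0.0868 in control cells, and more genes were called. The simulated shares may therefore not hold for these data, above all for comparisons with double KD cells. The 7-mer step found the planted 7-mer in 20 of 20 simulated runs.

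Alternatives planned beforehand were TMM factors, DESeq2's Wald test on recovered reads, no low-count filter and a stricter one, only the 2 groups compared, the replicate number as a block, non-robust variances, protein-coding genes alone, a fold threshold, fry and an estimated correlation for the lists, and each library left out in turn. Those added after seeing the data were edgeR on recovered reads, other pseudocounts, library weights, a correction for GC content and transcript length, the deposited log2 ratios, and list counts without double KD replicate 2. The single-gene results of 4 list members are not reported here, and these genes stay in the list tests and in all totals. edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.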

Results

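The transcriptome of MDA-MB-231 cells was measured in 12 RNA sequencing libraries: 3 each from control cells, SIRT1 KD cells, IGF2BP2 KD cells and double KD cells. SIRT1 is an NAD-dependent deacetylase, and IGF2BP2 is an RNA-binding protein that binds m6A-marked transcripts and stabilises many of them. The study asks which genes depend on each of these proteins. The gene ATP6V1A, which encodes the catalytic A subunit of the proton pump that acidifies lysosomes (the v-ATPase), was followed throughout because earlier work has linked its transcript to SIRT1 and IGF2BP2. Reads assigned to genes ranged from 19522606 to 22509142 in 11 libraries and came to 15243152 in double KD replicate 2. Values below are size-factor-normalised read counts with the SD over 3 libraries. On the first 2 principal components, which held 32.4% and 20.1% of the variance, libraries of a group lay together except double KD replicate 2. It stood apart from its partners, with an SD of its log2 values to their mean of 0.334, against 0.0979 to 0.213 in the other 11 libraries. Its mitochondrially encoded transcripts took 1.18% of reads, against 1.99% to 2.57% elsewhere. Its 10 most abundant genes took 8.53% of reads, against 6.06% to 7.32%.

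**Figure D1:**
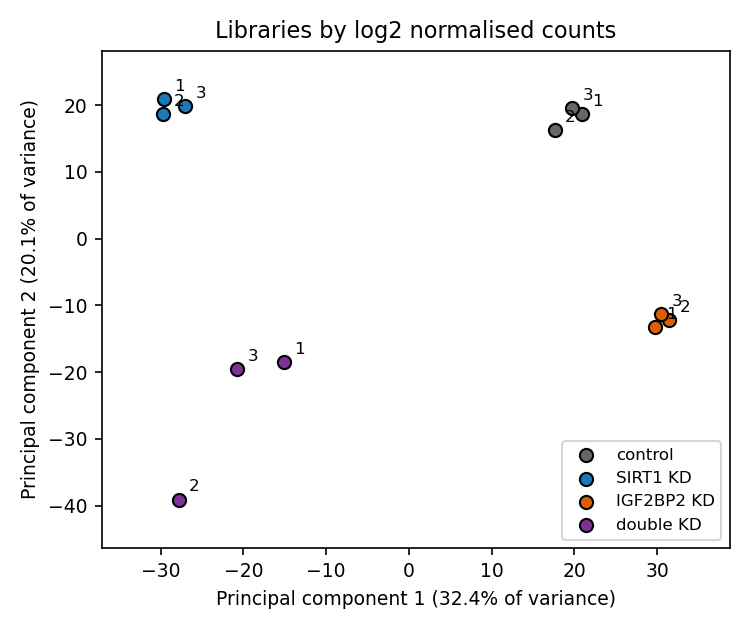
Each point is a library, placed by its scores on principal components 1 (32.4% of variance, horizontal axis) and 2 (20.1%, vertical axis) of the log2 normalised counts, with colours for the 4 groups and numbers for the replicates. Double KD replicate 2 lies apart from the other double KD libraries.

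The targeted transcripts were lower in the libraries meant to lack them. SIRT1 (ENSG00000096717.12, chromosome 10, 67884669 to 67918390, plus strand) was at 834 ± 32.7 normalised counts in control cells and 527 ± 27.5 in SIRT1 KD cells, a log2 fold change of -0.66 (95% interval -0.82 to -0.51, adjusted p = 4.3e-06). That is 63.2% of control. It was at 404 ± 28.7 in double KD cells, 48.5% of control (log2 fold change -1.05, SE 0.079, adjusted p = 1.1e-08), and at 728 ± 35.8 in IGF2BP2 KD cells, where the test did not call it (-0.20, adjusted p = 0.102). IGF2BP2 (ENSG00000073792.16, chromosome 3, 185643739 to 185825056, minus strand) was at 3076 ± 44.5 in control cells, 762 ± 69.6 in IGF2BP2 KD cells (24.7% of control, log2 fold change -2.02, adjusted p = 2.1e-10) and 864 ± 140 in double KD cells (27.9%, -1.84, adjusted p = 9.4e-11). It rose in SIRT1 KD cells to 3757 ± 35.4 (log2 fold change 0.29, SE 0.094, adjusted p = 0.0274). SIRT1 was also lower in double KD than in SIRT1 KD cells (-0.38, adjusted p = 0.00157), and IGF2BP2 in double KD did not pass the test against IGF2BP2 KD (0.17, 95% interval -0.01 to 0.36, adjusted p = 0.181). Every knockdown library lay below every control library for its target. SIRT1 was at 496 to 547 in SIRT1 KD and 380 to 436 in double KD libraries, against 799 to 863 in control. IGF2BP2 was at 709 to 841 in IGF2BP2 KD and 715 to 992 in double KD libraries, against 3045 to 3127 in control.

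**Figure D2:**
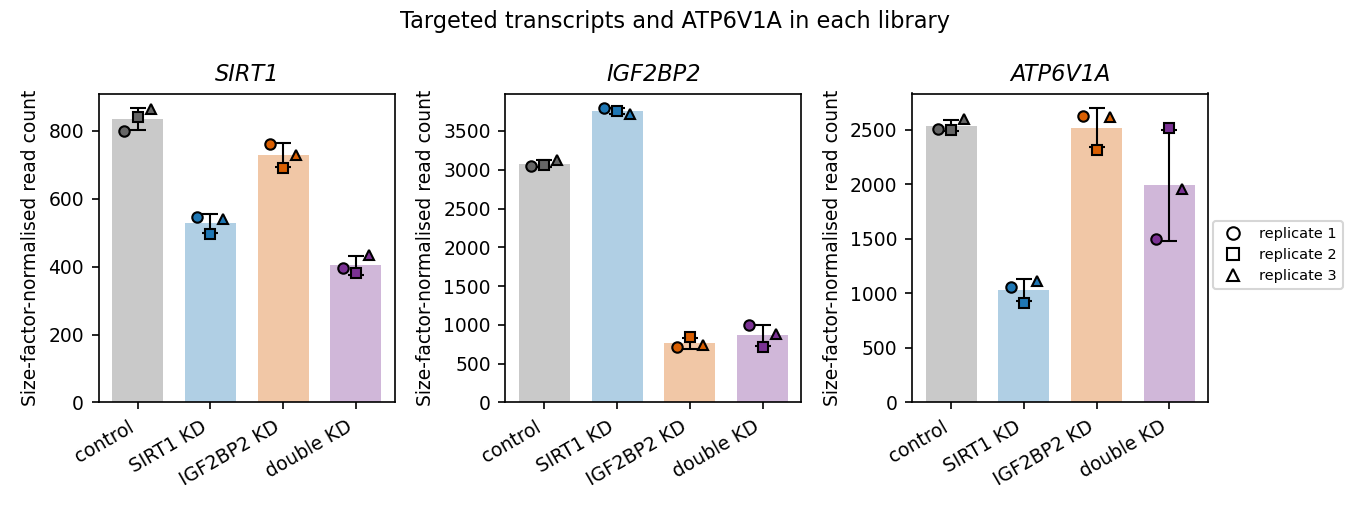
Size-factor-normalised read counts (vertical axes, starting at 0) of SIRT1, IGF2BP2 and ATP6V1A in the 4 groups; bars are means, error bars the SD over 3 libraries, and point shapes the replicates. SIRT1 falls in SIRT1 KD and double KD libraries, IGF2BP2 in IGF2BP2 KD and double KD libraries, and ATP6V1A is at 1028 in SIRT1 KD cells against 2535 in control cells.

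ATP6V1A (ENSG00000114573.10, chromosome 3, 113747019 to 113812056, plus strand) was at 2535 ± 51.7 in control cells and fell in SIRT1 KD cells to 1028 (1058, 916 and 1111 in replicates 1 to 3), 40.5% of control (log2 fold change -1.31, SE 0.135, adjusted p = 3.2e-06). In IGF2BP2 KD cells it was at 2519 ± 178 (-0.01, 95% interval -0.28 to 0.25, adjusted p = 0.968). In double KD cells the libraries differed widely, at 1495, 2513 and 1960 for replicates 1, 2 and 3, with a log2 fold change against control of -0.38 (SE 0.135, adjusted p = 0.0402). Against SIRT1 KD cells it was higher in double KD cells (0.92, adjusted p = 1.6e-04), and against IGF2BP2 KD cells lower (-0.37, adjusted p = 0.0492). The last call held only without SIRT1 KD replicate 2 or double KD replicate 2 among the 12 leave-one-out fits, and its adjusted p was 0.0535 to 0.177 in the other 10. The log2 fold change was -0.18 without double KD replicate 1 and -0.55 without double KD replicate 2. It was also lost in 7 other alternatives (0.0505 to 0.261). The 3′ UTR of ATP6V1A holds the sequence CTCAGATA at chromosome 3, 113811696 to 113811703, on the plus strand, in exon 15 of 15. The same sequence lies in the coding sequence of SIRT1 at chromosome 10, 67912495 to 67912502, on the plus strand, in exon 8 of 9, and genes with it in their 3′ UTR were lower as a group in SIRT1 KD cells, as given below. The call for double KD against control was lost without control replicate 1, 2 or 3 (adjusted p = 0.0825, 0.0792 and 0.0996), IGF2BP2 KD replicate 1 (0.0527) or double KD replicate 1 or 3 (0.151 and 0.0785). The log2 fold change then ranged from -0.39 to -0.19, and it was -0.57 without double KD replicate 2. The call was also lost with a replicate block (adjusted p = 0.0537), no filter (0.199), only the 2 groups (0.0875), the deposited ratios (0.132) and a GC and length correction (0.253).

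The v-ATPase subunits moved in both directions. Of 22 subunits measured, 5 rose and 3 fell in SIRT1 KD cells, ATP6V1A among the latter, both over all genes and adjusted over the list alone, and camera did not call the list (median 0.08, adjusted p = 0.37, and adjusted p = 0.85 with an estimated correlation). ATP6V0A1, a membrane-sector subunit, rose by 1.22 on the log2 scale (adjusted p = 4.1e-10) and ATP6V1B2 by 0.26 (adjusted p = 0.00535), while ATP6V1C1 fell by 0.37 (adjusted p = 7.6e-04). Among lysosomal membrane proteins LAMP1, an abundant glycoprotein, fell by 1.29 (adjusted p = 1.8e-10) and the sialic acid exporter SLC17A5 rose by 0.77 (adjusted p = 1.6e-07). Of 25 such proteins 7 rose and 5 fell (8 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.201, and adjusted p = 0.715 with an estimated correlation). Of 48 lysosomal hydrolases, 4 rose and 9 fell, with the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.701, and adjusted p = 0.904 with an estimated correlation). In a fit without double KD replicate 2, 9 v-ATPase subunits rose and 4 fell, and 10 hydrolases rose and 14 fell. The 3′ UTR of LAMP1 holds CTCAGAT.

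SIRT1 knockdown was compared with control to find the genes that depend on SIRT1. Among the largest rises were those of BSN and PCLO. These genes of scaffold proteins of the presynaptic active zone rose by 3.55 (adjusted p = 1.6e-09) and 2.17 on the log2 scale, and SCG2, a secretory granule protein, by 2.70. BSN went from 22.5 ± 4.54 to 272 ± 24.7 normalised counts. TMEM198, GOLGA7B and DISP2 rose by 3.35, 3.32 and 2.57, and HMGA2, an oncofetal chromatin protein and a known IGF2BP target, by 1.89, from 982 to 3654 counts. MARCHF4, C3orf14 and TNFSF15 rose by 1.58, 1.59 and 1.55. The largest falls were in SDC2, a heparan sulfate proteoglycan of the cell surface (-2.62, from 598 ± 7.06 to 98.3 ± 24.9 counts). Next came RPN2, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum (-2.42, from 6523 ± 152 to 1219 ± 74.2, adjusted p = 1.4e-14), and TMEM123 (-2.28). IFT52, FAM83A, MOB1A, PBXIP1, TSPAN9, CNIH1 and PROM2 had log2 fold changes of -1.75, -1.72, -1.72, -1.70, -1.70, -1.67 and -1.58, and each fell.

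Genes of cell division were lower in SIRT1 KD cells: 24 of 43 cell cycle and DNA replication genes fell and 0 rose (26 and 1 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 6.0e-07, and adjusted p = 0.715 with an estimated correlation). The securin PTTG1 fell by 0.81, the replicative helicase subunit MCM3 by 0.71 and the topoisomerase TOP2A by 0.64. Of 20 replication-dependent histone genes 12 fell and 0 rose (13 and 0 adjusted over the list alone), among them H1-2 by 0.68 and H2BC17 by 0.48 (median -0.38, adjusted p = 1.4e-05, and adjusted p = 0.626 with an estimated correlation). Leaving out 1 library, 7 histone genes fell without control replicate 2, 6 without SIRT1 KD replicate 2 and 20 without double KD replicate 2. Interferon-stimulated genes were lower too, with 16 of 28 falling and 0 rising, over all genes and adjusted over the list alone (median -0.39, adjusted p = 7.7e-06, and adjusted p = 0.626 with an estimated correlation). HERC5 fell by 1.01, OASL by 0.90, OAS2 by 0.68 and IFIT1 by 0.53.

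Genes of the unfolded protein and integrated stress response were lower in SIRT1 KD cells: 18 of 30 fell and 4 rose, over all genes and adjusted over the list alone (median -0.38, adjusted p = 1.8e-05, and adjusted p = 0.715 with an estimated correlation). The endoplasmic reticulum chaperones PDIA4, HSP90B1 and DNAJC3 fell by 1.15, 0.58 and 0.68, and SEL1L, an adaptor of protein degradation in that compartment, by 1.01. Of 30 mesenchymal and extracellular matrix genes 16 fell and 5 rose (17 and 6 adjusted over the list alone), including the matrix proteins THBS1 (-1.56) and TGFBI (-1.29) and the collagen cross-linking enzyme LOX (-1.22), with a median of -0.28 (adjusted p = 1.1e-04, and adjusted p = 0.626 with an estimated correlation). Of the 16 that fell, 10 hold CTCAGAT or TCAGATA in the 3′ UTR, and 11 of all 30 members do. Among stress response genes 6 of the 18 that fell hold at least 1, and 7 of all 30. The numbers were 5 of 24 and 5 of 43 for cell cycle genes, and 3 of 16 and 4 of 28 for interferon-stimulated genes. Of all searched genes 20.1% hold at least 1. The 7-mers were picked by their z in this same comparison, as given below. The carbonic anhydrases CA9 and CA12 and the oxygen sensor EGLN3 led the glycolysis and hypoxia list, by -1.54, -1.08 and -1.15. Of 32 members 13 fell and 4 rose (14 and 4 adjusted over the list alone, median -0.08, adjusted p = 0.0269, and adjusted p = 0.715 with an estimated correlation). This call was lost without SIRT1 KD replicate 2 (adjusted p = 0.0801, median -0.05). Of 54 cytosolic ribosomal protein genes 5 rose, led by RPS24 (0.27), and 0 fell (3 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.00287, and adjusted p = 0.798 with an estimated correlation). Those that rose numbered 2 or 3 without any 1 control library or SIRT1 KD replicate 1 or 3, 9 without double KD replicate 1 and 22 without double KD replicate 2.

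Some single genes moved while their lists were not called. MYC, FOSL1 and DUSP1 rose by 0.75, 0.60 and 0.60 in SIRT1 KD cells, with 6 of 20 immediate-early and heat-shock genes higher and 4 lower (7 and 5 adjusted over the list alone, adjusted p = 0.11). The p53 target BTG2 rose by 1.17 and MDM2 fell by 0.75, with 11 of 26 p53 targets higher and 4 lower (11 and 7 adjusted over the list alone, adjusted p = 0.146; 7 lower without double KD replicate 2). RRAGD and FNIP2, regulators of nutrient signalling at the lysosome, rose by 0.85 and 0.93, with 10 of 37 autophagy and MiT/TFE genes higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 0.118; 6 lower without double KD replicate 2). SIRT2 rose by 0.54, and 1 of 7 sirtuins was higher and 1, SIRT1, lower (adjusted p of the list = 0.636; 2 higher without double KD replicate 2). IDI1, an enzyme of cholesterol synthesis, fell by 1.28, with 6 of 25 genes of that list higher and 3 lower (adjusted p = 0.729; 5 lower without double KD replicate 2).

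In total 5030 of 17576 genes changed in SIRT1 KD cells, 2272 higher and 2758 lower, and 478 of them by at least 2-fold, 126 higher and 352 lower (limma, 3 libraries per group). The number was 7794 with only the SIRT1 KD and control libraries in the fit. The SIRT1 transcript was at 63.2% of control in these cells.

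Genes whose 3′ UTR holds the 7-mers CTCAGAT or TCAGATA were lower in SIRT1 KD cells than genes without them. Of 16247 7-mers CTCAGAT had the lowest z (-21.1) and TCAGATA the next lowest (-17.5); together they spell CTCAGATA. In IGF2BP2 KD cells z was 0.23 and -0.03, and in double KD cells -14.9 and -12.5. For double KD against IGF2BP2 KD, which shares no library with SIRT1 KD against control, z was -16.2 and -13.5. The 374 genes with CTCAGATA had a median log2 fold change of -0.28, the 2259 with a 7-mer but not the joined sequence -0.13, and the 10498 with neither 0.02. Of 2633 genes with either 7-mer 37.6% fell, against 14.3% of the others. Both 7-mers were picked by their z in SIRT1 KD against control itself. These medians and shares, and the matches among the largest falls, are therefore no independent check. SDC2, RPN2, TMEM123, IFT52, FAM83A, MOB1A, PBXIP1, TSPAN9, CNIH1 and PROM2, the 10 largest falls, all hold at least 1 of these 7-mers, which 20.1% of all searched genes hold; of the 10 largest rises GOLGA7B, HMGA2 and TNFSF15 do.

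**Figure D3:**
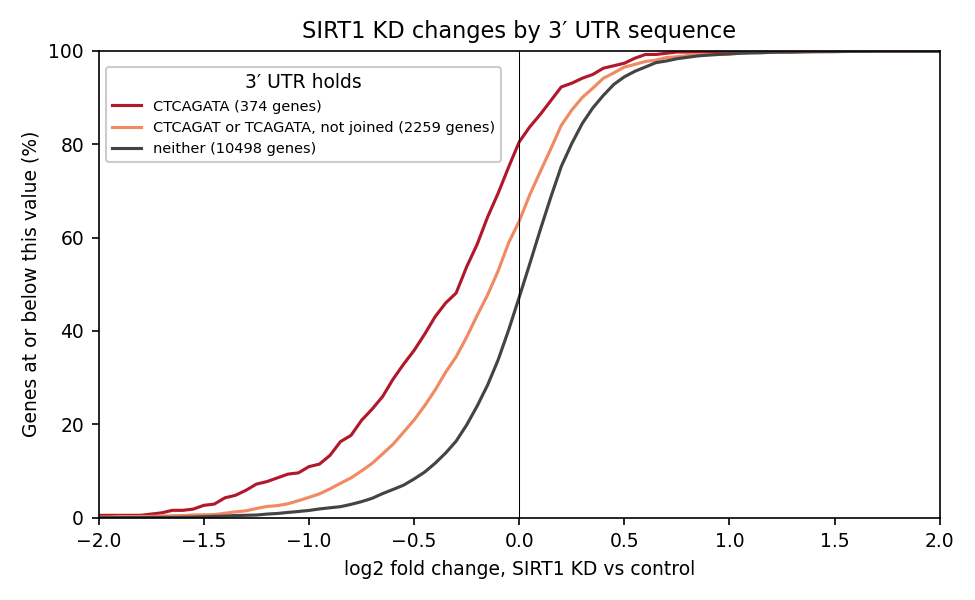
Cumulative share of genes (vertical axis, percent) at or below each log2 fold change of SIRT1 KD against control (horizontal axis), for genes whose 3′ UTR holds CTCAGATA (374 genes), CTCAGAT or TCAGATA but not the joined sequence (2259) or neither (10498). The curves are shifted to lower values in that order, with medians of -0.28, -0.13 and 0.02. The sequences were picked by their z in this same comparison.

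IGF2BP2 knockdown was compared with control to find the genes that depend on IGF2BP2. Secreted inflammatory signals fell: IL24 from 542 ± 18.6 to 172 ± 8.03 normalised counts (-1.65, adjusted p = 3.9e-09), the neutrophil chemokine CXCL8 (-1.65), CXCL2 (-1.14) and IL6 (-1.13). Of 22 NF-kB target and inflammatory secretome genes measured, 14 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.50, camera adjusted p = 3.0e-10, and adjusted p = 0.307 with an estimated correlation). AREG, a ligand of the epidermal growth factor receptor, fell by 1.86 and the tight junction protein CLDN1 by 1.86, with SRI, KISS1, SERINC2, RPL7L1 and PI4K2B lower, at -1.60, -1.46, -1.43, -1.42 and -1.39. The largest rise was in ATOH8, a basic helix-loop-helix transcription factor (2.22, adjusted p = 5.1e-08), followed by the mucin MUC5AC (1.32), FAM222B (1.21), the iron exporter SLC40A1 (1.08) and the pro-apoptotic BMF (1.05). FAM234B, ANKRD52, the DNA demethylase TET2, SOX4 and ROBO1 rose by 0.96, 0.95, 0.95, 0.94 and 0.94.

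Stress response, protease and vesicle genes were also lower in IGF2BP2 KD cells. Of 30 unfolded protein and integrated stress response genes 16 fell and 0 rose (18 and 0 adjusted over the list alone, median -0.31, adjusted p = 1.7e-09, and adjusted p = 0.537 with an estimated correlation), among them CHAC1 (-0.92), the serine synthesis enzyme PSAT1 (-0.57) and the chaperones HSPA5 (-0.55) and HSP90B1 (-0.35). Of 19 secreted proteases and inhibitors 8 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.21, adjusted p = 8.9e-05, and adjusted p = 0.609 with an estimated correlation). The plasminogen activators PLAU and PLAT were at -0.75 and -0.72, SERPINE2 at -0.91 and TIMP3 at -0.64. Of 20 immediate-early and heat-shock genes 8 fell, such as DUSP1 (-0.73) and IER2 (-0.51), and 1 rose (10 and 1 adjusted over the list alone, median -0.19, adjusted p = 0.00169, and adjusted p = 0.939 with an estimated correlation). Of 42 ESCRT and exosome biogenesis genes 9 fell and 2 rose (12 and 2 adjusted over the list alone, median -0.09, adjusted p = 0.00847, and adjusted p = 0.976 with an estimated correlation). Those that fell included the vesicle traffic GTPases RAB27A (-0.67) and RAB11A (-0.49) and the syntenin gene SDCBP (-0.42). Those that fell numbered 15 without double KD replicate 2.

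Transcripts described elsewhere as bound by IGF2BP proteins did not fall together in IGF2BP2 KD cells: of 9 measured, 4 rose and 2 fell, over all genes and adjusted over the list alone (median 0.12, adjusted p = 0.22). HMGA1 fell by 0.57, and HMGA2, CCND1 and MARCKSL1 rose by 0.70, 0.38 and 0.47. The paralog IGF2BP3 rose by 0.62 (adjusted p = 3.2e-05) in the list of IGF2BP family and m6A machinery, of which 1 member of 21 rose and 3 fell, IGF2BP2 itself included (adjusted p = 0.987; 3 rose without double KD replicate 2). GALC, a lysosomal galactosidase, fell by 1.29 and NEU1 by 0.85, while CTSA rose by 0.42. Of 48 hydrolases 10 rose and 4 fell (13 and 6 adjusted over the list alone, adjusted p = 0.524; 11 fell without double KD replicate 2). The p53 and stress target GDF15 fell by 1.23, with 5 of 26 p53 targets higher and 5 lower (6 and 9 without double KD replicate 2). VEGFA, which encodes a growth factor of blood vessels, fell by 0.87. Of 32 glycolysis and hypoxia genes 4 rose and 6 fell (15 and 7, with a median of 0.11, without double KD replicate 2). Neither list was called.

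In IGF2BP2 KD cells 2857 of 17576 genes changed, 1206 higher and 1651 lower, and 164 by at least 2-fold, 56 higher and 108 lower (limma, 3 libraries per group). The number was 5116 with only the IGF2BP2 KD and control libraries in the fit, 5037 without double KD replicate 2, 1892 without control replicate 2 and 1862 without control replicate 3. The 7-mers AGCGGTA and GGTAATA had the lowest z of all 7-mers in this comparison (-11.4 and -10.5; -1.17 and -0.10 in SIRT1 KD cells, -9.43 and -5.82 in double KD cells). They overlap in AGCGGTAATA, which lies in the 3′ UTR of IGF2BP2 at chromosome 3, 185645063 to 185645072, on the minus strand. IGF2BP2, SRI and PI4K2B, among the 10 largest falls, hold at least 1 of these 7-mers, as do 9.05% of all searched genes. These 7-mers were picked by their z in this same comparison, so that number is no independent check.

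Genes changed by both single knockdowns moved in the same or in opposite directions about equally often. Of the genes called in both comparisons with control, 301 were higher in both, 394 lower in both and 672 opposite, where independent lists of these sizes would share 156, 259 and 403. The opposite share was 49.2%, and independent lists give 49.2%. The 3 counts were 181, 206 and 372 at the lowest (without control replicate 1, 3 and 1) and 699, 754 and 1358 without double KD replicate 2. Each moved by over 1.5 times without any 1 control library, and the first also without IGF2BP2 KD replicate 1 or 3. LOX was lower in both (-1.22 and -1.03), and CLDN1 was at 247 counts in SIRT1 KD, 124 in control and 34.4 in IGF2BP2 KD cells. Across genes the log2 fold changes correlated with r = 0.0986, against 0.497 for simulated unchanged groups that share these 3 controls, and the covariance differed from the simulated one by -0.00758; genes are not independent replicates. The 3 controls cannot be parted into sets of at least 2, so these numbers include what the shared controls add. The simulation drew its noise with the spread shared by all groups (median residual SD 0.153). That is wider than the spread of the control libraries (median SD 0.0868). The simulated covariances may therefore exceed what the shared controls add, so a negative difference decides nothing. Against the double KD changes, r was 0.632 for SIRT1 KD, with 0.501 for simulated unchanged groups. Of genes called in both, 1459 were higher in both, 1664 lower in both and 144 opposite. Independent lists would share 380, 483 and 859. For IGF2BP2 KD r was 0.437, with 0.498 simulated (638, 909 and 224 genes, with 202, 289 and 487 from independent lists). The simulated r is that of groups without real changes, so an r below it does not speak against shared changes. The covariance differences were 0.0992 for SIRT1 KD and 0.0462 for IGF2BP2 KD.

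Double KD cells were compared with control to see the changes with both shRNAs. Genes that fell in either single knockdown were among the largest falls: SDC2 (-2.53), IL24 (-2.47, from 542 to 97.2 ± 9.74 counts), AREG (-2.46), TGFB2 (-2.24), LOX (-2.23, from 2616 ± 87.1 to 556 ± 48.8, adjusted p = 4.1e-13), CXCL8 (-2.13), and SORBS2, IGFBP1, LGALS12 and ICMT at -2.26, -2.08, -2.07 and -2.05. SDC2, SORBS2, TGFB2, LOX, CXCL8 and ICMT hold a 7-mer of the SIRT1 KD comparison and SORBS2, LOX and ICMT also one of the IGF2BP2 KD comparison. Of the 10 largest rises, GOLGA7B, HMGA2 and DCP2 hold a 7-mer of the former comparison, and GOLGA7B and DCP2 a 7-mer of the latter. Of all searched genes 20.05% and 9.05% do. TMEM198, GOLGA7B, DISP2, BSN and PCLO rose by 2.75, 2.63, 2.15, 2.02 and 1.65. NR6A1, an orphan nuclear receptor of germ cells and embryos, rose by 2.36, from 178 in control to 395 in SIRT1 KD, 303 in IGF2BP2 KD and 919 counts in double KD cells. HMGA2, ANKRD52, the mRNA decapping enzyme DCP2 and the kinase MAPK11 rose by 1.82, 1.71, 1.65 and 1.60.

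The stress response genes were lower in double KD cells than in control cells or in either single knockdown. Against control 25 of 30 fell and 1 rose (27 and 1 adjusted over the list alone, median -0.59, adjusted p = 2.9e-14, and adjusted p = 0.422 with an estimated correlation). SEL1L, HSPA5, DNAJC3 and HSP90B1 were at -1.39, -1.21, -1.06 and -1.03. The median was -0.76, -0.52 and -0.63 in double KD replicates 1, 2 and 3. Of 19 secreted proteases and inhibitors 11 fell and 0 rose, over all genes and adjusted over the list alone (median -0.59, adjusted p = 2.0e-05, and adjusted p = 0.511 with an estimated correlation). That median was -0.30 without double KD replicate 1 and -0.37 without replicate 3. PLAT, PLAU and SERPINE2 were at -1.57, -1.17 and -1.14 and the sheddase ADAM17 at -0.92. Of 22 NF-kB and secretome genes 12 fell and 4 rose, over all genes and adjusted over the list alone (median -0.50, adjusted p = 5.4e-04, and adjusted p = 0.511 with an estimated correlation), with IL6 at -2.05. Of 30 mesenchymal and matrix genes 13 fell and 4 rose (13 and 5 adjusted over the list alone, median -0.22, adjusted p = 5.0e-04, and adjusted p = 0.511 with an estimated correlation), with THBS1 at -1.53 and CCN2 at -1.39.

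Metabolic and interferon genes moved as well in double KD cells. Of 32 glycolysis and hypoxia genes 17 fell and 3 rose (17 and 4 adjusted over the list alone, median -0.17, adjusted p = 5.4e-04, and adjusted p = 0.836 with an estimated correlation), with VEGFA, P4HA1, SLC2A3 and LDHA at -1.18, -0.88, -0.83 and -0.71. The median was -0.30 without double KD replicate 2. Of 28 interferon-stimulated genes 14 fell and 3 rose (16 and 3 adjusted over the list alone, median -0.31, adjusted p = 0.00205, and adjusted p = 0.511 with an estimated correlation), with OASL, HERC5, OAS2 and IFIT3 at -0.99, -0.84, -0.69 and -0.68. Of 46 nuclear-encoded oxidative phosphorylation genes 11 rose, such as ATP5F1B (0.37), and 4 fell, such as COX6A1 (-0.77), over all genes and adjusted over the list alone (median 0.18, adjusted p = 0.0372, and adjusted p = 0.836 with an estimated correlation). That median was -0.02, 0.34 and 0.14 in double KD replicates 1, 2 and 3, and the call was lost without double KD replicate 2 (adjusted p = 0.41, median 0.06), double KD replicate 3 (0.0644), control replicate 1 (0.0628) or control replicate 2 (0.0519). Those that rose numbered 4, 7 and 6 without control replicate 1, 2 and 3, and 26 without double KD replicate 1. Histones (median -0.19, adjusted p = 0.0601; 0 rose and 4 fell of 20), ribosomal proteins (-0.06, adjusted p = 0.125; 0 and 8 of 54) and mitochondrially encoded genes (-0.30, adjusted p = 0.185; 0 and 1 of 13) were not called. Their medians in replicate 2 were 0.14, 0.16 and -1.10, against -0.33, -0.27 and 0.11 in replicate 1 and -0.16, -0.06 and 0.13 in replicate 3. Without replicate 2 the histones (17 of 20 lower, adjusted p = 7.4e-05) and ribosomal proteins (32 of 54 lower, adjusted p = 7.4e-05) were called, though not with an estimated correlation (adjusted p = 0.931 for both), and the mitochondrial median was 0.14. Transcripts described as IGF2BP-bound were not called (median 0.22, adjusted p = 0.0601; 0.11 and 0.159 without replicate 2), with CCND1 higher by 0.94. In total 6018 of 17576 genes changed, 2939 higher and 3079 lower (limma, 3 libraries per group). Of these, 700 changed by at least 2-fold, 158 higher and 542 lower. The number of changed genes was 7068 without double KD replicate 2, and 4426 with only the double KD and control libraries in the fit. Of the changed genes 51.5% were higher without double KD replicate 1.

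**Figure D4:**
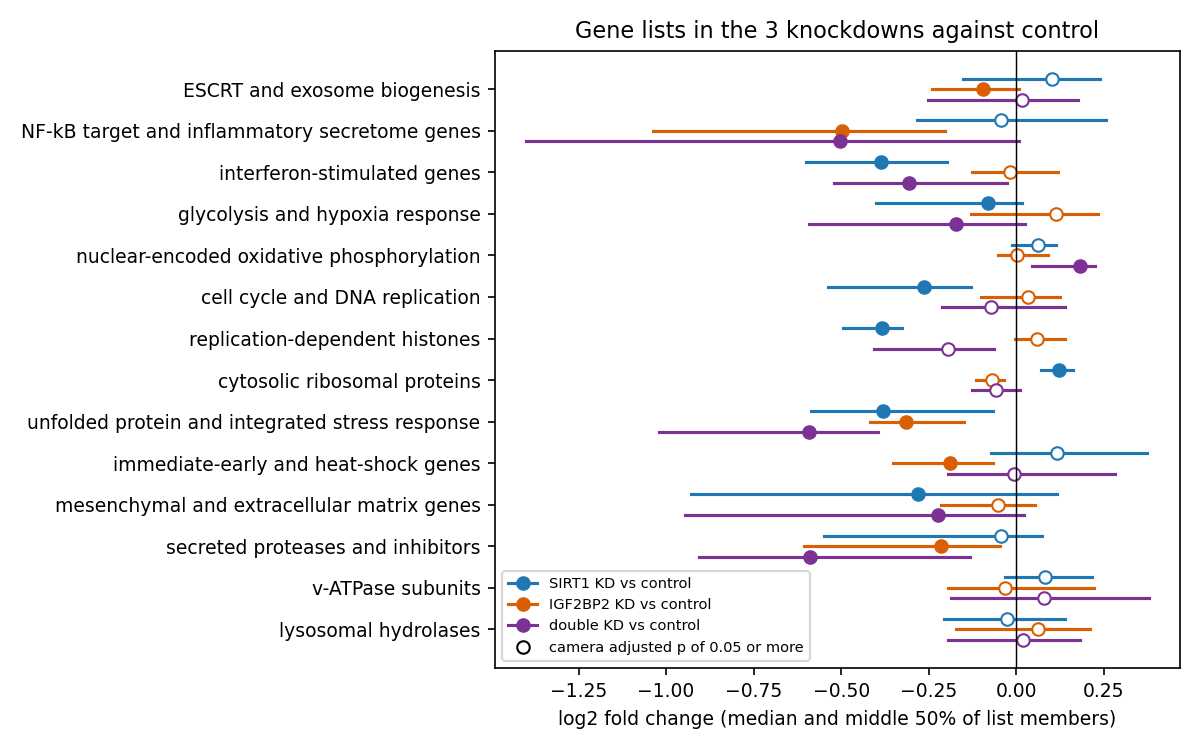
Log2 fold change (horizontal axis) of gene list members in SIRT1 KD, IGF2BP2 KD and double KD cells against control: points are medians over the members, lines span the middle 50% of members, and open points are lists that camera did not call. Stress response genes have medians of -0.38, -0.31 and -0.59, and NF-kB and secretome genes of -0.04, -0.50 and -0.50.

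Double KD cells were compared with each single knockdown to see what differed with the added knockdown. SIRT1 was lower in double KD than in SIRT1 KD cells, and no group is described with a targeting and a sham hairpin together. The added knockdown therefore cannot be told apart from the load of a further hairpin or, against SIRT1 KD, from deeper SIRT1 loss. Against SIRT1 KD, CLDN1, SCG2, IL24, IGF2BP2 and CXCL8 had the largest falls (-2.39, -2.38, -2.35, -2.13 and -2.07), and ATOH8, PROM2, ITGB2, AMMECR1 and CDS1 the largest rises (1.83, 1.59, 1.53, 1.51 and 1.35). Of 22 NF-kB and secretome genes 12 fell and 0 rose (13 and 0 adjusted over the list alone, median -0.53, adjusted p = 1.8e-09, and adjusted p = 0.373 with an estimated correlation). Of 30 stress response genes 19 fell, DNAJB9 by 0.88 among them, and 0 rose (20 and 0 adjusted over the list alone, median -0.35, adjusted p = 1.8e-09, and adjusted p = 0.491 with an estimated correlation). Of 19 secreted proteases and inhibitors 10 fell and 0 rose, likewise adjusted over the list alone (median -0.29, adjusted p = 1.3e-05, and adjusted p = 0.491 with an estimated correlation), with TIMP3 at -1.20. Cell cycle genes were higher than in SIRT1 KD cells, with 19 of 43 rising and 2 falling, likewise adjusted over the list alone (median 0.22, adjusted p = 1.2e-06, and adjusted p = 0.821 with an estimated correlation), among them CDC6 (0.81) and MCM4 (0.70). Histones were higher (5 of 20 rose, 0 fell, likewise adjusted over the list alone, median 0.28, adjusted p = 0.0131, and adjusted p = 0.821 with an estimated correlation), a call lost without SIRT1 KD replicate 2 (0.0511). The histone median was 0.11 without double KD replicate 2. Those that rose numbered 2, 0 and 3 without SIRT1 KD replicate 1, 2 and 3, and 11 without double KD replicate 1.

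Ribosomal protein genes were lower in double KD than in SIRT1 KD cells (19 of 54 fell, 0 rose, 21 and 0 adjusted over the list alone, median -0.18, adjusted p = 3.9e-08, and adjusted p = 0.821 with an estimated correlation), led by RPS4X (-0.97). Without double KD replicate 2 the number that fell was 49 and the median -0.28, and without replicate 1 the median was -0.08. Without SIRT1 KD replicate 1 or 3, 10 or 12 fell. Mitochondrially encoded genes were lower (2 of 13 fell, MT-ND3 and MT-ND4L by 0.48 and 0.24, and 0 rose, likewise adjusted over the list alone, median -0.54, adjusted p = 1.5e-04, and adjusted p = 0.821 with an estimated correlation), with 9 lower and a median of -0.19 without replicate 2, 4 lower without replicate 3 and 1 lower without SIRT1 KD replicate 1 or 3. FOXO targets were lower (7 of 19 fell, 1 rose, likewise adjusted over the list alone, median -0.10, adjusted p = 0.012, and adjusted p = 0.502 with an estimated correlation), among them FBXO32, a ubiquitin ligase subunit, at -0.68. Cholesterol synthesis genes (9 of 25 fell, 1 rose, 9 and 2 adjusted over the list alone, median -0.07, adjusted p = 0.0486, and adjusted p = 0.879 with an estimated correlation) included HMGCS1 at -0.58. The cholesterol call was lost with a replicate block (adjusted p = 0.054), and without control replicate 1 or 3 (0.0538 and 0.0532), SIRT1 KD replicate 1 or 3 (0.0975 and 0.0785), IGF2BP2 KD replicate 1 or 3 (0.0513 and 0.0527) or double KD replicate 1 (0.407). Its median was -0.03 without SIRT1 KD replicate 3 or double KD replicate 1, -0.11 without double KD replicate 2 and -0.13 without double KD replicate 3, and 4 or 5 fell without SIRT1 KD replicate 1 or 3. In total 3980 genes changed, 2093 higher and 1887 lower, and 2214 with only these groups in the fit. Of the 308 changed by at least 2-fold, 104 were higher and 204 lower. CTCAGAT, the lowest 7-mer in SIRT1 KD cells, had the highest z of all 7-mers in this comparison (4.99). The share of changed genes that were higher was 52.6%, and 47.5% without SIRT1 KD replicate 2 or double KD replicate 3.

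Against IGF2BP2 KD, GOLGA7B, TMEM198, DISP2, BSN and MARCHF4 had the largest rises (2.81, 2.75, 1.85, 1.85 and 1.81), and LGALS12, SDC2, the formyl peptide receptor FPR1, TSPAN9 and RPN2 the largest falls (-2.58, -2.44, -2.10, -2.06 and -2.04). Glycolysis and hypoxia genes were lower (18 of 32 fell, 2 rose, 20 and 2 adjusted over the list alone, median -0.29, adjusted p = 5.1e-06, and adjusted p = 0.664 with an estimated correlation), with CA12 at -1.33 and ALDOC at -1.13. Of 30 stress response genes 15 fell, SEL1L by 1.22 among them, and 2 rose (15 and 3 adjusted over the list alone, median -0.24, adjusted p = 5.1e-06, and adjusted p = 0.664 with an estimated correlation). Of 28 interferon-stimulated genes 14 fell, IFIT1 by 0.54 among them, and 2 rose (15 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.00265, and adjusted p = 0.664 with an estimated correlation). Of 30 mesenchymal and matrix genes 12 fell and 3 rose (12 and 4 adjusted over the list alone, median -0.20, adjusted p = 0.00265, and adjusted p = 0.664 with an estimated correlation), with THBS1 at -1.49 and a median of -0.13 without double KD replicate 2. Of 20 histones 8 fell and 0 rose, likewise adjusted over the list alone (median -0.22, adjusted p = 0.00413, and adjusted p = 0.787 with an estimated correlation), with H1-2 at -0.47. The histone median was -0.06 without double KD replicate 1 and -0.36, with 19 lower, without replicate 2.

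Secreted proteases and cholesterol synthesis genes were lower in double KD than in IGF2BP2 KD cells too. The sheddase ADAM17 was at -0.70, and 9 of 19 of the protease list fell and 2 rose (11 and 3 adjusted over the list alone, median -0.24, adjusted p = 0.0146, and adjusted p = 0.787 with an estimated correlation). IDI1 was at -1.27, and 10 of 25 cholesterol synthesis genes fell and 2 rose, likewise adjusted over the list alone (median -0.10, adjusted p = 0.016, and adjusted p = 0.818 with an estimated correlation). Mitochondrially encoded genes were lower in double KD than in IGF2BP2 KD cells (1 of 13 fell, MT-ND3 by 0.38, and 0 rose, likewise adjusted over the list alone, median -0.47, adjusted p = 0.00772, and adjusted p = 0.826 with an estimated correlation). That call was lost without double KD replicate 2 (0.197, median -0.07), and the median was -0.71 without replicate 3. Those that fell numbered 2, 5 and 3 without double KD replicate 1, 2 and 3. Immediate-early and heat-shock genes were higher (10 of 20 rose, 2 fell; 10 and 4 adjusted over the list alone, median 0.20, adjusted p = 0.0374, and adjusted p = 0.818 with an estimated correlation). EGR1 was at 1.10 and DUSP1 at 1.07. The call was lost without double KD replicate 2 (0.067), double KD replicate 3 (0.0549) or IGF2BP2 KD replicate 3 (0.0766). The cholesterol median was -0.16 without IGF2BP2 KD replicate 2, -0.22 without double KD replicate 2 and -0.17 without double KD replicate 3. Without double KD replicate 1 the cholesterol (0.12), histone (0.0552) and protease (0.0552) calls were lost. In total 5550 genes changed, 2885 higher and 2665 lower, and 3641 with only these groups in the fit. Of the 565 changed by at least 2-fold, 156 were higher and 409 lower. The share that were higher was 49.3% without double KD replicate 3.

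The interaction asks whether the effect of IGF2BP2 knockdown differed between SIRT1 KD and control cells. Only double KD cells carry both hairpins, so the load of a further hairpin can enter this contrast too. MUC5AC was at 209 ± 7.68 counts in control, 525 ± 37.6 in SIRT1 KD, 525 ± 41.7 in IGF2BP2 KD and 181 ± 18.3 in double KD cells, an interaction of -2.85 on the log2 scale (SE 0.137, adjusted p = 1.2e-09). SCG2 (-1.99), BSN (-1.70), the hyaluronan synthase HAS2 (-1.34) and the nuclear receptor NR4A2 (-1.19) had the other largest negative values. The largest positive interaction was that of the retinoic acid hydroxylase CYP26B1, at 138, 84.1, 112 and 196 counts in the same order of groups (SE 0.192, adjusted p = 6.3e-04). HTR1D (1.06), EVA1A (1.06), PLEKHG4 (1.01) and TENT5B (1.00) followed. ATP6V1A had an interaction of 0.94 (SE 0.191, 95% interval 0.56 to 1.31, adjusted p = 0.0183), a call lost without control replicate 2 or 3 (adjusted p = 0.0576 and 0.0517) or IGF2BP2 KD replicate 2 (0.0543). It was also lost with no filter (0.114), the deposited ratios (0.103) and a GC and length correction (0.103). Its value ranged from 0.75 to 1.13 over the 12 leave-one-out fits. For SIRT1 and IGF2BP2 themselves the interaction was -0.19 (adjusted p = 0.396) and -0.12 (adjusted p = 0.696).

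Cell cycle genes had a positive interaction (10 of 43 positive, 0 negative; 19 and 0 adjusted over the list alone, median 0.28, adjusted p = 5.0e-09, and adjusted p = 0.76 with an estimated correlation). PCNA was at 0.67, CDC6 at 0.68, MCM6 at 0.61 and MCM4 at 0.57. Mitochondrially encoded genes had a negative interaction (2 of 13 negative, 0 positive, likewise adjusted over the list alone, median -0.73, adjusted p = 5.0e-08, and adjusted p = 0.76 with an estimated correlation). So did ribosomal proteins (2 of 54 negative, 0 positive, 9 and 0 adjusted over the list alone, median -0.09, adjusted p = 8.9e-06, and adjusted p = 0.863 with an estimated correlation). Cholesterol synthesis genes had a negative one too (2 of 25 negative, 0 positive, 6 and 0 adjusted over the list alone, median -0.18, adjusted p = 2.2e-05, and adjusted p = 0.76 with an estimated correlation). The interaction was also negative for glycolysis and hypoxia genes (4 of 32 negative, 0 positive, 11 and 1 adjusted over the list alone, median -0.18, adjusted p = 3.5e-04, and adjusted p = 0.863 with an estimated correlation), and for FOXO targets (3 of 19 negative, 0 positive, 4 and 0 adjusted over the list alone, median -0.15, adjusted p = 0.00258, and adjusted p = 0.76 with an estimated correlation). RPS4X was at -0.70, NDRG1 at -0.48 and the cell cycle inhibitor CDKN1B at -0.50. The ribosomal protein call was lost without double KD replicate 1 (0.0939), where the median turned to 0.01, and without replicate 2 the median was -0.22. The glycolysis and hypoxia median was -0.12 without double KD replicate 1. The mitochondrial median in double KD replicate 2 was -1.10 against control, while replicates 1 and 3 were at 0.11 and 0.13; without replicate 2 their median interaction was -0.32, and 12 of 13 had a negative one. These genes were then called higher in SIRT1 KD (11 of 13, median 0.24, adjusted p = 2.9e-04) and IGF2BP2 KD cells (8 of 13, 0.18, 8.3e-04), though not with an estimated correlation (0.802 and 0.991). With all libraries neither was called (adjusted p = 0.11 and 0.22). Also without replicate 2, 19 ribosomal protein, 11 cholesterol synthesis and 14 glycolysis and hypoxia genes had a negative interaction, and 18 cell cycle genes a positive one. Fewer were called in most fits without a control, SIRT1 KD or IGF2BP2 KD library, down to 1 cell cycle, 0 mitochondrial, 1 ribosomal, 1 cholesterol synthesis, 1 glycolysis and hypoxia and 1 FOXO gene. Without double KD replicate 3, 10 ribosomal and 4 cholesterol synthesis genes were called, and without replicate 1 16 cell cycle genes.

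In total 503 genes had an interaction, 299 positive and 204 negative, 52 of them of at least 2-fold (22 positive, 30 negative). The positive share was 59.4%, and 48.1% without SIRT1 KD replicate 2 and 49.2% without double KD replicate 3. The number moved by over 1.5 times without each library but IGF2BP2 KD replicate 1 and double KD replicate 3. It ranged from 113 without control replicate 2 to 1771 without double KD replicate 2, was 926 with DESeq2 and 109 on the deposited log2 ratios, and 583 with edgeR on recovered reads.

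Markers of other cell types were not called as lists in any of the 6 comparisons. The lowest adjusted p was 0.276 for epithelial and luminal markers (double KD against control), 0.631 for fibroblast markers and 0.133 for immune cell markers (both double KD against IGF2BP2 KD), and 0.608 for packaging-cell markers (double KD against SIRT1 KD). Few of their members were measured: 12 of 24, 4 of 9, 2 of 12 and 2 of 10. PDGFRB, a growth factor receptor of mesenchymal cells in the fibroblast list, fell by 1.39 in SIRT1 KD cells, and COL1A1 rose by 0.54. Without double KD replicate 2 the epithelial list was called against control (9 of 12 lower, adjusted p = 0.0223) and against SIRT1 KD (adjusted p = 0.0131), though not with an estimated correlation (0.931 and 0.781).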

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

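The tests without double KD replicate 2, of SIRT1 shRNA activity, of shuffled and sign-flipped residuals, of GC and length in double KD replicate 2 and of cells without shRNA were chosen only after the results they address were seen. Listed here is each result in which the effect of 1 knockdown differed with the other, by the limma test of the interaction.

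There were 503 genes with an interaction, and 2 of 100 regroupings (other splits) of the 12 libraries, the real one included, gave as many. The highest other gave 1545 genes, and in it the interaction contrast falls on libraries with against libraries without the IGF2BP2 shRNA. Regrouping also mixes real group differences into the spread, whose median residual SD was 0.258 against 0.153 in the real groups, so it decides nothing on chance here. Shuffling the residuals of a fit without interaction keeps both knockdown effects, and the real order was the 1 of 100 with as many genes (highest other 1). It needs noise between libraries around additive effects of the 2 knockdowns to be alike in all groups, but the median SD within a group was 0.2 in double KD and 0.0868 in control cells, so this too decides nothing. Flipping the sign of whole libraries' residuals allows noise of unequal size between libraries around additive effects of the 2 knockdowns: 2 of 100 flips, the real signs included, gave as many genes, the highest other 678, which argues against such noise as the source of the count. For the 5 comparisons of 3 libraries with 3, the real split was the 1 of 10 with as many changed genes as observed, at 5030 for SIRT1 KD against control, 2857 for IGF2BP2 KD against control, 6018 for double KD against control, 3980 for double KD against SIRT1 KD and 5550 for double KD against IGF2BP2 KD. The highest other split gave 0 in each, and 10 splits are too few for a share under 0.05.

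Log2 interactions were 1.5 for CYP26B1, 1.06 for HTR1D, 1.06 for EVA1A, 1.01 for PLEKHG4 and 1 for TENT5B. They were -2.85 for MUC5AC, -1.99 for SCG2, -1.7 for BSN, -1.34 for HAS2 and -1.19 for NR4A2. Among gene lists the median interaction was 0.2755 for cell cycle genes, -0.7306 for mitochondrially encoded genes, -0.08607 for ribosomal proteins, -0.1843 for cholesterol synthesis, -0.184 for glycolysis and hypoxia and -0.1484 for FOXO targets. Without double KD replicate 2 the mitochondrial median was -0.324 and the ribosomal one -0.222, and without double KD replicate 1 the ribosomal one was 0.0091.

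ATP6V1A had a log2 interaction of 0.936: it was at 40.5% of control in SIRT1 KD cells and 76.8% in double KD cells. Without double KD replicate 2 the interaction was 0.751 (SE 0.133, adjusted p = 0.00171), which argues against that library as its cause. Weaker activity of the SIRT1 shRNA beside another shRNA would lift genes with its seed match. CTCAGATA is taken as that match here, but it was picked from these data, and the hairpin sequence is not given in the sources used here. Relative to genes without either 7-mer, the 307 other genes with CTCAGATA at a mean of at least 5 CPM regained 17.1% of their loss. The share was 18.9% for all 373. ATP6V1A regained 71.7%, taken without that reference, more than these genes did as a group. The 95% bootstrap interval of 7.26% to 27.9% drew genes, not libraries, and leaves out the spread between libraries. The median of the 307 genes against control was -0.23, -0.327 and -0.179 in double KD replicates 1, 2 and 3. It was lowest in replicate 2, where ATP6V1A was highest. The share was not computed without replicate 2. Of the 307 genes, 31 fell to within 0.3 of the ATP6V1A log2 fold change or further. Their median regain was 13.25%, and 0 of them regained as large a share as ATP6V1A. SIRT1 itself was lower in every double KD library than in every SIRT1 KD library, as given above. Both argue against weaker activity as the whole cause, while a partial contribution stays open. After removal of GC content and length trends the interaction of ATP6V1A was 0.942, but its SE rose from 0.191 to 0.298. The limma adjusted p rose from 0.0183 to 0.103, so this bias cannot be told apart. An effect of IGF2BP2 loss on ATP6V1A in cells with the SIRT1 shRNA stays open as a biological explanation, untested here.

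Double KD replicate 2 stood apart, with an SD to its partners of 0.334. Thinning all libraries to 15243152 reads left that SD at 0.336, the highest of the 12 (next 0.217, double KD replicate 1), which argues against depth. A share of cells without shRNA would raise both targets, but IGF2BP2 was at 715 and SIRT1 at 380, the lowest of the 3 double KD libraries, which argues against it. GC content and length trends took out 42.8% of the variance and left an SD of 0.253 (next 0.177, double KD replicate 1), which argues against them as the whole cause. As part of the cause they cannot be told apart, since their share lies between what the test needed for and against. No biological explanation was tested, since the labels give no difference between the 3 libraries.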

How the results depend on the processing

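The edgeR test, other pseudocounts, library weights, the GC and length correction and the deposited ratios are tests chosen only after the data were seen. No called value of a named gene and no called list turned direction in any alternative run for it, by the test's own direction. The uncalled ATP6V1A change in IGF2BP2 KD cells ran from -0.04232 to 0.04853 without 1 library. The median interaction of ribosomal proteins was 0.009097 without double KD replicate 1, and 42.3% of interactions were positive at a log2 size of at least 1, against 59.4% of all. The cause of each shift below was not tested unless its construction shows it. Depth limits genes near the count filter, mostly in double KD replicate 2 with 15243152 reads.

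With only the 2 groups compared the changed genes numbered 7794 (SIRT1 KD against control) and 5116 (IGF2BP2 KD against control), more than with all libraries. They numbered 4426 (double KD against control), 2214 (double KD against SIRT1 KD) and 3641 (double KD against IGF2BP2 KD), fewer than with all libraries. The fit with all libraries gives each gene 1 spread for the 4 groups. The median SD within a group was 0.2 in double KD cells and 0.0868 to 0.113 in the other groups. By these medians the shared spread is too wide for the single knockdown comparisons and too narrow for those with double KD cells. A log2 fold change of at least 1 left 478, 164, 700, 308, 565 and, for the interaction, 52, by its construction. Library weights gave 7937 and 6778 for the single knockdowns and 2577 interactions. The interaction count was 926 with DESeq2, 109 on the deposited ratios of protein-coding genes and 1265 after the GC and length correction.

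The ATP6V1A change in double KD against control was past the threshold with all libraries and not with no filter (-0.3814, adjusted p = 0.199), only the 2 groups (-0.3814, 0.0875), the deposited ratios (-0.3626, 0.132) or the GC and length correction (-0.3372, 0.253). With a replicate block it was -0.3814 (adjusted p = 0.0537), and the replicate block gave 5098, 2930, 6083, 4072 and 5655 changed genes in the 5 comparisons and 457 interactions. A pairing of libraries by replicate number was not seen, but this check cannot exclude one, since GC content trends of single libraries can hide it. Libraries with the same number correlated at a mean r of 0.0102 over 18 pairs, and 6 of 12 were closest to their own number. The ATP6V1A interaction lost its call with no filter (0.9358, adjusted p = 0.114), the deposited ratios (0.9519, 0.103) and the GC and length correction (0.9419, 0.103).

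Gene lists past the test numbered 7, 5, 7, 9 and 9 in the 5 comparisons and 6 for the interaction. With camera and an estimated correlation they numbered 0 in all 6, where 1, 2, 1, 2, 0 and 1 lists had an unadjusted p under 0.05. With fry they numbered 13 (SIRT1 KD against control), 13 (double KD against control), 5 (double KD against SIRT1 KD), 14 (double KD against IGF2BP2 KD) and 0 (interaction, where 3 had an unadjusted p under 0.05 with fry).

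Leaving out each library in turn, IGF2BP2 KD against control ran from 1862 (without control replicate 3) to 5037 (without double KD replicate 2), and the interaction from 113 (without control replicate 2) to 1771 (without double KD replicate 2). ATP6V1A ran from -0.566 (without double KD replicate 2) to -0.1914 (without double KD replicate 1) in double KD against control, and from 0.7512 to 1.126 without the same libraries in the interaction. Shared genes of the single knockdowns ran from 181 (without control replicate 1) to 699 higher in both, 206 (without control replicate 3) to 754 lower in both and 372 (without control replicate 1) to 1358 opposite, each highest without double KD replicate 2.

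Of 579 called values of named genes 578 kept their call with TMM factors, 576 with edgeR, 574 with the replicate block, 568 with the GC and length correction and 552 with no filter, and 531 to 577 without 1 library. On the deposited ratios 518 of 578 did, with only the 2 groups compared 504 of 529 and with DESeq2 577 of 578. Of 43 list calls 43 held with TMM factors, 42 with the replicate block and 38 to 43 without 1 library. Of the same 43, 29 also passed fry in the same direction, but fry tests a list against no change, not against other genes. The number of called members moved by over 1.5 times in 4 to 11 of the 43 called lists without 1 control, SIRT1 KD or IGF2BP2 KD library, always down, and in 5, 12 and 4 without double KD replicate 1, 2 and 3, always up. Lists called without double KD replicate 2 but not with all libraries, beyond those in the report, were ESCRT (adjusted p = 0.00686), glycolysis and hypoxia (0.00427) and immediate-early genes (0.0104) lower in double KD than SIRT1 KD, hydrolases (0.0239) and ribosomal proteins (0.00584) lower in double KD than IGF2BP2 KD, and hydrolases (0.0171) and NF-kB genes (0.0292) negative in the interaction, none of them with an estimated correlation (0.781 to 0.904).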

Other observations

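The tests of microRNA sites and the genes named in the first 2 paragraphs were chosen only after the results were seen. The 7-mers and joined sequences used below were picked by the scan of all 7-mers in these data. Tests of these sequences in SIRT1, IGF2BP2 and ATP6V1A were therefore not fixed before that scan was seen.

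A transcriptional repressor was lower in SIRT1 KD cells. REST, which silences neuronal genes outside neurons, fell by 0.68 in SIRT1 KD (limma adjusted p = 1.0e-05), by 0.60 in double KD against control (2.9e-05) and was at 0.01 in IGF2BP2 KD cells (adjusted p = 0.956). Its cofactor RCOR1 fell by 0.48 in SIRT1 KD (4.9e-05) and by 0.55 in double KD cells (8.9e-06). The 3′ UTR of REST holds TCAGATA and that of RCOR1 holds CTCAGATA.

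For the microRNA pathway 3 genes were looked at, without a test of the group. AGO2, which carries microRNAs to their targets and whose 3′ UTR holds CTCAGAT, rose by 0.76 in IGF2BP2 KD (4.0e-07) and 0.66 in double KD cells (4.7e-07). DICER1, which cuts microRNA precursors, rose by 0.67 (2.9e-06) and 0.99 (5.2e-09), and XPO5, which exports them, rose by 0.53 in double KD cells (2.2e-06) and was at -0.01 in IGF2BP2 KD cells (adjusted p = 0.955). In SIRT1 KD cells AGO2 was at 0.11 (adjusted p = 0.257), DICER1 at 0.18 (0.0602) and XPO5 at 0.30 (0.00103).

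The sequences in the genes that fell may reflect off-target activity of the hairpins. CTCAGAT had the lowest z of all 7-mers in SIRT1 KD cells (-21.12) and AGCGGTA in IGF2BP2 KD cells (-11.43), each low again in double KD cells and not in the other knockdown, as a microRNA-like seed match predicts. The joined IGF2BP2 sequence is in IGF2BP2 and in 0.0455% of protein-coding genes, as a target site would be; the joined SIRT1 sequence is in SIRT1 but also in 6.76%, too many for its presence to count. ATP6V1A holds CTCAGATA, and 6.19% of the 307 other genes with it at a mean of at least 5 CPM fell as far (5.63% of all 373). At or below -1.3 were 5.88% of genes with CTCAGATA and 0.543% of genes with neither 7-mer. Most genes with CTCAGATA fell less than ATP6V1A, with a median of -0.28. A direct effect of the hairpin could therefore account for the fall of ATP6V1A, or only for a part of it, without SIRT1. SIRT1-dependent loss stays open, since hairpin sequences are not given in the sources used here and no other SIRT1 hairpin was analysed here.

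A hypothesis for genes that rose in double KD cells is that hairpins compete with the cells' own microRNAs. The matches of 14 abundant microRNA families had a median z of 2.11 in double KD cells, 13 of 14 above 0, and 0 of 10000 random sets of 14 7-mers were as high. The median was 1.82 in SIRT1 KD and 1.35 in IGF2BP2 KD cells, and -0.38 for the interaction. This is consistent with weaker microRNA activity, but the control also carries a hairpin, and microRNAs were not analysed here.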
